A study of Mus musculus with 14 samples.

How the data were processed

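RNA from the uterus of 8-week-old C57BL/6 mice was measured on 14 Illumina mouse BeadChip arrays of 45281 probes. Per the labels, 5 arrays held non-pregnant uterus, 5 held pregnant uterus of mice given PBS, and 4 held pregnant uterus of mice given PC61. Both pregnant groups were collected 12 days after fertilization. PC61 is an antibody against CD25, the alpha chain of the interleukin-2 receptor, and is used to deplete regulatory T cells. The labels' protocols give homogenization in a bead mill, extraction with Trizol and RNeasy columns with DNase I, a Bioanalyser check, and biotin-labelled cRNA made with the Ambion MessageAmp kit. The labels number the replicates of each group, but nothing says that the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

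The deposited scanner table gives, per the file headers, 1 average intensity and 1 detection p-value for each probe and array. The deposited intensity values were not normalized between arrays, and none was at or below 0. The deposited detection p-value moved in steps of the reciprocal of 936, the number of negative controls it would rank against. The authors' series matrix holds log2 values of 16948 of the probes. The software and the background step behind either table are not given in the sources used here. The column medians of the matrix lay between 7.96 and 7.99 and its values between 6.51 and 15.06. The rank correlation of each matrix column with the intensities of its own array was 1, and a quantile normalization of the log2 intensities of all probes came within a median difference of 0.109 of it. Its scale was therefore read as log2, with genes not centred and larger values meaning more signal, while the exact normalization and the rule that chose its probes stay unknown. It left out 1979 probes detected on every array, and was used as an alternative source of values.

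Intensities were processed in limma 3.58.1 under R 4.3.3 with neqc, which fits a normexp background model, adds an offset of 16, applies quantile normalization and takes log2. The background was inferred from the detection p-values, since control probes were not used here. Probes with a detection p under 0.01 on at least 4 of the 14 arrays were kept, which left 20967. Symbols came from the platform annotation of the matrix probes and were brought up to date through Entrez identifiers, which matched 15463 probes and changed 0 symbols. Of the scanner probes, 15469 had 1 symbol, 5 had several and were not named, and 29807 were unnamed here, among them 1474 of the matrix probes. Each gene was represented by its probe of highest mean over all arrays, which gave 10478 genes tested, of which 3547 had several kept probes. Some genes had probes past the threshold in opposite directions: 34 between PBS and non-pregnant arrays, 4 between PC61 and non-pregnant arrays and 0 between PC61 and PBS arrays. No probe named here held Il2ra, the gene of the PC61 target, and it was not analysed here.

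Differences between groups were tested with limma, using lmFit with 1 mean for each of the 3 groups and eBayes, with 11 residual and 3.40 prior degrees of freedom. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 was called a change. A positive log2 fold change means a higher level in the group named first. A probe with no array of a group under the detection threshold has only a bound there. Its fold is given as at least N-fold, from the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the probe's own value and the lowest value of any detected probe on that array. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.225 between PC61 and PBS arrays and 0.212 between PBS and non-pregnant arrays.

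The groups, the tests, 29 gene lists, the processing alternatives and the rule for named genes were fixed before the data were examined. That rule took the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold whose groups did not overlap. Where fewer than 5 genes passed, it took the 5 of lowest p in each direction. It added up to 4 members of lowest p from each list, and always Il2ra and Foxp3. Predicted genes and clone names were skipped. A few genes outside the rule, shown by array, were chosen after their values were seen. They are Psg21 and Prl8a2 in the comparison of PC61 with PBS, and Hoxc10 and Hoxd12.

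The lists were tested with camera from limma at a preset inter-gene correlation of 0.01, over the 28 lists with at least 5 measured members. The list of B and plasma cell genes had 4 and was not tested as a list. Of their measured members, 0 of 22 trophoblast and placental and 0 of 18 smooth muscle genes stood in another list, 1 of 12 erythroid and yolk sac and 1 of 8 liver and pancreas genes (Ttr in both), and at most 3 of any other list. Camera compares the genes of a list with all others. It was run again with the correlation estimated from the data, and fry, which asks whether the genes of a list move on balance in 1 direction, was run beside it. Members were also counted after adjustment over the list alone. List levels on single arrays are the mean difference of the members from their PBS mean on the log2 scale. The relation between the PC61 and the pregnancy effect was the median Spearman correlation across genes over 20 splits of the PBS arrays in which no array entered both effects. Genes are not independent replicates, so this value has no p.

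The fits were tested on simulated data before use. In 10 simulations of the comparison of PC61 with PBS on 10478 genes, with the pooled residual spread of each gene on every array, limma called 55.8% of the genes given a log2 change of 1, 91.5% of those given 2 and 97.0% of those given 3. The real PC61 arrays were more spread than the PBS arrays, with a median SD of 0.403 against 0.242. These shares therefore give no measure of how often real changes on the PC61 arrays were missed. A gene not called is not shown to be unchanged. In 20 simulations of a list shifted in every array of a group, camera called it each time with either correlation, as fry did. The genes of that list varied independently there, while the estimated correlation of the real smooth muscle list was 0.591 and that of trophoblast genes 0.776. These simulations therefore give no measure of how often real lists are missed with an estimated correlation. A list not called there is not shown to be unchanged. A list shifted on single arrays without regard to group was called in 11 of 20 simulations by camera at the preset correlation and in 0 with the estimated correlation or fry.

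The alternatives were no background correction, an offset of 50, median scaling or cyclic loess in place of quantile normalization, the authors' matrix values, 2 other filters on detection, each probe by itself, a trended and robust variance, array weights, the pair of groups alone, a fold minimum, a stricter threshold, the replicate number as a block, and each array left out. The fit without the 2 arrays of lowest median signal was added after the data were seen. Slide was not used as a block, since no slide is given in the sources used here. Figures were drawn with matplotlib 3.10.9.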

Results

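Uterine RNA was profiled on 14 Illumina BeadChip arrays in 3 groups: 5 from non-pregnant mice, 5 from PBS-treated pregnant mice and 4 from pregnant mice treated with PC61, an anti-CD25 antibody used to deplete regulatory T cells. Both pregnant groups were taken 12 days after fertilization. The median probe intensity ranged from 93.0 to 139 between arrays. Between 16607 and 19729 probes were detected, and the PC61 arrays lay within this range with 17483, 19136, 18378 and 19580. Across the 10478 genes tested, pairwise correlations were 0.940 to 0.989 among non-pregnant arrays, 0.971 to 0.987 among PBS arrays and 0.861 to 0.981 among PC61 arrays. The median SD of a gene was 0.251 in the non-pregnant, 0.242 in the PBS and 0.403 in the PC61 group. An SD above 1 on the log2 scale was found for 1156 genes in the PC61 group, 247 in the non-pregnant group and 2 in the PBS group. The first principal component, with 63.2% of the variance, placed the PBS arrays between 56.2 and 58.6 and the non-pregnant arrays between -74.4 and -73.1. PC61 arrays 1 to 4 lay at 18.7, -0.344, 2.25 and 64.5 on it.

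The first comparison, stated in the series design, asked how the pregnant uterus after PC61 differed from the PBS-treated pregnant uterus. Genes of the placenta were lower in the PC61 group, with a median log2 fold change of -3.21 over 22 measured trophoblast and placental genes, all of which were lower. Embryonic blood and yolk sac genes were lower by a median of -1.66 over 12 genes, and smooth muscle genes were higher by a median of 1.03 over 18. These differences were unequal between the 4 PC61 arrays. No single gene of 10478 passed limma's test, where the lowest adjusted p was 0.154. Foxp3, the transcription factor of regulatory T cells, had a log2 level of 9.30 ± 0.37 (SD, n = 4) in the PC61 group, 9.36 ± 0.14 (n = 5) in the PBS group and 9.34 ± 0.16 (n = 5) in the non-pregnant group. Its log2 fold change was -0.06 with a limma adjusted p of 0.887, and it was detected on all 14 arrays. Of 9 measured T cell genes, 4 were not above background in the PC61 or the PBS group. Among them, Cd3e lay at 4.40 to 4.80 and Cd3g at 4.35 to 4.83 on the PBS arrays. Whether the much brighter Foxp3 probe reports regulatory T cells in this tissue was not tested.

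The trophoblast and placental list was lower in camera's test (adjusted p = 4.14e-17), and the call was lost at adjusted p = 0.469 with an estimated correlation. Over all genes tested 0 of the 22 members passed, while 20 fell when adjusted over the list alone. Plac1, a gene named for its placental expression, had a log2 fold change of -3.75 (SE 0.86) and Dlx3, a homeobox gene of the placenta, had -3.11 (SE 0.71). Synb and Syna encode syncytins, which fuse trophoblast cells, and their values were -2.83 (SE 0.65) and -1.82 (SE 0.43). All 4 had an adjusted p of 0.154. All were above background on every PBS array, and among the 4 PC61 arrays Dlx3 was on 3 and Synb and Syna on 1. The mean level of the list relative to the PBS mean was -4.93, -4.83, -2.86 and 0.61 on PC61 arrays 1 to 4, against -0.26 to 0.29 on the PBS arrays and -5.67 to -5.58 on the non-pregnant arrays. Psg21, a pregnancy-specific glycoprotein, had log2 levels of 4.46, 4.39, 11.29 and 14.58 on the same 4 arrays, and 13.84 to 14.20 on the PBS arrays. PC61 array 4 was the only PC61 array without a fall. With it left out the list median was -4.38 and the list passed with an estimated correlation too (adjusted p = 0.00858). On the 3 arrays left, Plac1, picked for its low p, stood at -5.12 (limma adjusted p = 1.18e-08). Leaving out the array that went the other way favours such calls, so they are no independent support. Each other pregnant array left out gave 0 lists with an estimated correlation.

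The erythroid and yolk sac list was lower in camera's test (adjusted p = 2.59e-06; adjusted p = 0.469 with an estimated correlation), and 6 of its 12 members fell when adjusted over the list alone. Hba-x and Hbb-bh1, embryonic globins, had log2 fold changes of -1.61 (SE 0.44) and -1.76 (SE 0.52). Tfrc, the transferrin receptor, had -1.12 (SE 0.36) and Ttr, a thyroid hormone carrier made by yolk sac and liver, had -2.01 (SE 0.71). List levels were -0.12, -2.81, -2.46 and -0.01 on PC61 arrays 1 to 4 and -0.07 to 0.09 on the PBS arrays. The liver and pancreas list was also lower, with a median of -2.03 over 8 genes (adjusted p = 0.000715; adjusted p = 0.469 with an estimated correlation). The 6 members that fell when adjusted over the list alone included Apob, Apoa1, Apoa2 and Fga, which encode secreted plasma proteins that the yolk sac also makes. Cell cycle genes had a median of -0.52, with 21 of 23 lower (adjusted p = 0.000808; adjusted p = 0.679 with an estimated correlation), and levels of 0.36, -1.02, -1.18 and -0.06 on PC61 arrays 1 to 4, against -0.05 to 0.04 on the PBS arrays. Among them Mcm2 and Mcm3, parts of the helicase that licenses DNA replication, had -0.68 and -0.78. The cell cycle call was lost without PC61 array 3, where the median was -0.31.

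Smooth muscle genes rose as a list in camera's test (adjusted p = 1.2e-06; adjusted p = 0.507 with an estimated correlation). Of the 18 measured, 17 were higher, and 7 rose when adjusted over the list alone. Smtn, which encodes smoothelin of contractile muscle, had a log2 fold change of 1.23 (SE 0.33), Lmod1, an actin filament nucleator, 1.73 (SE 0.47), Cnn1, calponin, 1.01 (SE 0.28), and Kcnmb1, a potassium channel subunit, 1.06 (SE 0.34). Cnn1 was above background on 3 PC61 arrays and 1 PBS array, and the other 3 on every array of both groups. The list level was 1.24, 1.34, 1.19 and -0.64 on PC61 arrays 1 to 4, against -0.19 to 0.26 on the PBS arrays. With PC61 array 4 left out the smooth muscle median was 1.49, and this list passed with an estimated correlation (adjusted p = 0.0359). That array was the only PC61 array without a rise, so leaving it out favours the call. Extracellular matrix genes rose as a list with a median of 0.49 over 27 genes (adjusted p = 0.00253; adjusted p = 0.679 with an estimated correlation), a call lost without PC61 array 3 (median 0.29). Timp2, an inhibitor of matrix proteases, and Loxl1, a collagen and elastin crosslinker, were each higher by 0.81 (SE 0.34 and 0.36).

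Of the lists of immune genes, 4 rose in camera's test, and immediate early genes rose as a list too. The interferon gamma response and MHC class I list had a median of 0.63, with 19 of 20 genes higher (adjusted p = 0.000228; adjusted p = 0.584 with an estimated correlation). Irgm2 and Igtp, interferon-induced GTPases, were higher by 0.80 (SE 0.31) and 0.69 (SE 0.30). All 10 measured cytokine genes were higher, with a median of 0.46 (adjusted p = 0.000836; adjusted p = 0.469 with an estimated correlation). Osm, oncostatin M, at 1.36 (SE 0.35) and Il1b, interleukin-1 beta, at 1.37 (SE 0.44) were the 2 cytokine genes that rose when adjusted over the list alone. Both were above background on 3 of the 4 PC61 arrays, Osm on 2 PBS arrays and Il1b on 1. Cytokine levels were 0.17, 1.03, 1.22 and 0.00 on PC61 arrays 1 to 4 and -0.12 to 0.08 on the PBS arrays. Immediate early genes had a median of 0.60 (adjusted p = 0.00053; adjusted p = 0.509 with an estimated correlation), with Hspa1a, a heat shock chaperone, at 0.97 and Egr2, a growth response factor, at 1.19, and with levels of 0.00, 1.14, 1.10 and -0.02 on the same PC61 arrays. Chemokine genes had a median of 0.46 (0.38 with members at their bound, adjusted p = 0.0216; adjusted p = 0.509 with an estimated correlation), with Ccl4 at 1.62 and Ccl5 at 1.05, and levels of -0.01, 0.74, 0.95 and -0.06. The dendritic cell and MHC class II list had a median of 0.80 (adjusted p = 0.036; adjusted p = 0.584 with an estimated correlation), with H2-Aa, an MHC class II chain, at 1.01 and Batf3, a transcription factor of cross-presenting dendritic cells, at -1.51, and levels of 0.09, 0.76, 1.01 and -0.33. Both of these last calls were lost without PBS array 2 (chemokine median 0.55, MHC class II median 0.80), without PC61 array 2 (0.35 and 0.61) and without PC61 array 3 (0.26 and 0.33). Interferon gamma response levels were -0.35, 1.18, 1.44 and -0.07 on PC61 arrays 1 to 4 and -0.13 to 0.12 on the PBS arrays.

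The other 17 lists did not pass camera's test (adjusted p = 0.0546 to 0.949). Regulatory T cell genes had a median of 0.26 over 7 genes (0.17 with members at their bound, adjusted p = 0.79), which ranged from -0.06 to 0.93 over 28 other settings. Levels of this list were -0.92, 0.40, 0.66 and -0.07 on PC61 arrays 1 to 4 and -0.06 to 0.09 on the PBS arrays. On PC61 array 1 Tnfrsf9, a costimulatory receptor, was at 4.41, against 9.64 to 10.20 on the PBS arrays, and Foxp3 at 9.83. NK cell and granule genes had a median of 0.22 (adjusted p = 0.461), with levels of -2.33, 1.29, 1.21 and -0.05 on PC61 arrays 1 to 4. Gzmd, a granzyme of uterine NK cells, was at 4.83, 14.76, 14.67 and 14.14 on these arrays, and at 14.12 ± 0.17 (SD, n = 5) on the PBS arrays. Decidual genes had a median of 0.09 and a mean of -0.12 (adjusted p = 0.949), and endothelial genes had a median of 0.14 and a mean of -0.02 (adjusted p = 0.743), with camera's direction up for both. Medians were 0.18 for T cell, 0.31 for mast cell and eosinophil, -0.17 for neutrophil, 0.23 for complement, -0.25 for cholesterol and steroid synthesis, -0.08 for glycolysis and hypoxia and -0.04 for adipocyte genes. Prl8a2, a prolactin-related hormone of the decidua, stood at 5.80 on PC61 array 1 and at 13.54 to 13.60 on the other 3. Without PC61 array 1, calls were gained for NK cell (median 0.92), macrophage (0.43), type I interferon (0.76), tolerance (0.48), contraction-associated (0.91) and skeletal muscle (-0.59) lists, while camera with an estimated correlation called 0 lists there. Without PBS array 1, where an estimated correlation also left 0 lists, they were gained for macrophage (0.36), type I interferon (0.32) and endometrial epithelial (-0.49) genes. Leaving out PC61 array 3 added the endometrial epithelial list (-0.43, with 0 lists at an estimated correlation), and leaving out PC61 array 4 added the macrophage list (0.54, adjusted p = 0.556 with an estimated correlation).

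**Figure D1:**
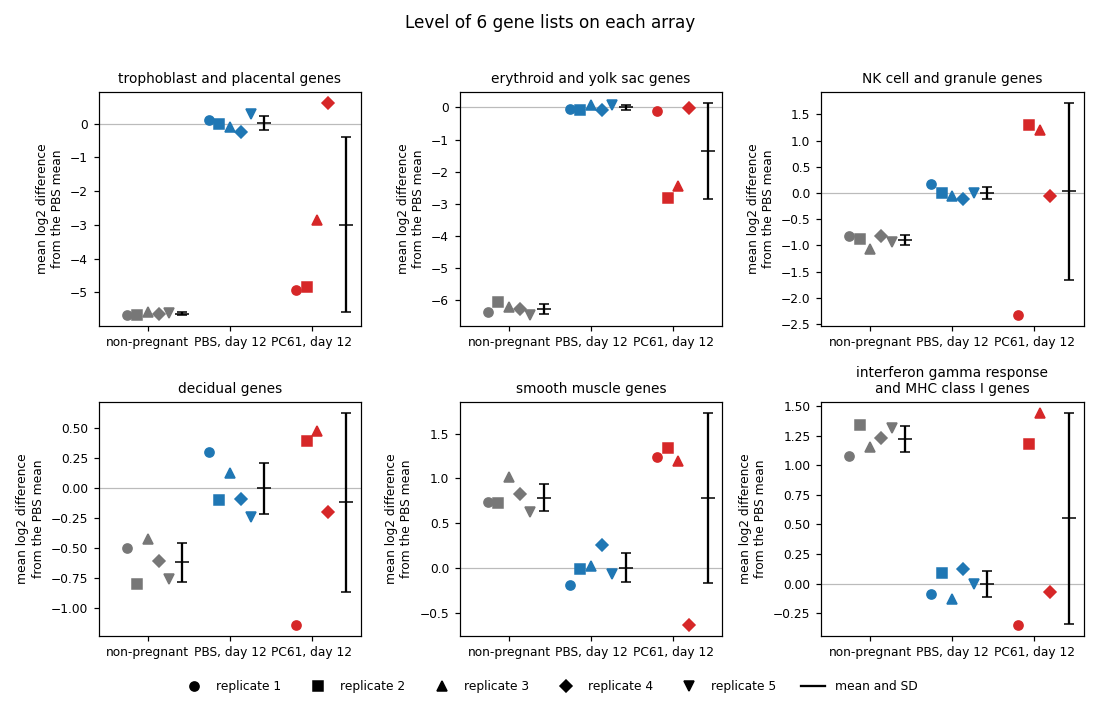
Mean log2 difference from the PBS mean for the members of 6 gene lists on each of the 14 arrays, by group, with marker shapes for replicate numbers and black bars for group mean and SD. The trophoblast and placental level lay between -4.93 and 0.61 on the 4 PC61 arrays and between -0.26 and 0.29 on the PBS arrays.

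Among single genes, those of lowest p that were higher after PC61 were Slc5a3, a myo-inositol transporter, at 1.18 (SE 0.24), Ankrd12 at 0.90 (SE 0.20), Snx32 at 0.72 (SE 0.16), Fcer2a, the low-affinity IgE receptor, and Abca7, a lipid transporter, at 0.86 (SE 0.20). Fcer2a was not above background on any PBS array and was at least 1.53-fold higher on the PC61 arrays. Those lower were Doxl2 at -1.06 (SE 0.19), Nkain1 at -1.15 (SE 0.21), Ugt3a2, a glycosyltransferase, at -1.33 (SE 0.25), Unc5b, a netrin receptor, at -1.37 (SE 0.26), and Pdap1 at -0.93 (SE 0.18). None passed, each with a limma adjusted p of 0.154. Slc5a3 was above background on 2 PBS arrays, and on the PC61 arrays Doxl2 and Ugt3a2 were on 1 and Nkain1 on 3. Outside the lists that passed, Krt8 and Krt18, keratins of simple epithelia, had -1.80 and -1.24, Flt1, a VEGF receptor, had -1.36, and Cyp17a1, a steroid hydroxylase, had -2.90.

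By limma, 0 genes passed at adjusted p under 0.05 between PC61 and PBS arrays. At an unadjusted p under 0.05 there were 1624 genes (768 higher, 856 lower), or 15.5% against 5% by chance. The groups did not overlap for 191 genes, 1.82% against 1.59% by chance. The count was 0 in most other settings, but 303 with median scaling (all lower, with a median of all genes of -0.30), 4039 with array weights (2111 higher, 1928 lower), 1528 without PC61 array 4 (815 higher, 713 lower) and 2 without PC61 array 1. Those 2 were the homeobox genes Hoxd12 (log2 fold change -1.84, adjusted p = 0.000215) and Hoxc10 (-1.84, adjusted p = 0.00971). Without PC61 array 4, 73 of 125 genes named by the rule passed, among them each of the 10 genes of lowest p, against 1528 of all 10457 genes. The rule had picked these genes for low p in this comparison on the same arrays, so their larger share is no independent support. Camera called 11 of 28 lists, camera with an estimated correlation 0 and fry 0, against 14 lists at an unadjusted p under 0.05 in camera. Without PC61 array 1, camera called 17 lists and fry 11, and fry called 10 without PC61 array 4. Each of the 11 lists kept the sign of its median in the 28 other settings, but the sizes varied. Settings that changed only the test, such as fry or the estimated correlation, could not change the median. Medians lay between 0.28 and 1.30 for interferon gamma response, 0.14 and 0.72 for cytokine, 0.27 and 1.09 for immediate early, 0.23 and 1.08 for chemokine and 0.29 and 1.33 for MHC class II genes. They lay between -4.38 and -2.41 for trophoblast, -2.66 and -0.92 for erythroid, -3.60 and -1.12 for liver and pancreas, and -1.07 and -0.28 for cell cycle genes. For smooth muscle and extracellular matrix genes they were 0.79 to 1.54 and 0.21 to 0.81.

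The second comparison set PBS-treated pregnant uterus against non-pregnant uterus. At day 12 the largest rises included embryonic globins and placental genes, and the largest falls included Plekhs1, P2ry14, Fxyd4 and Sprr2f. Limma called 4887 of 10478 genes, 2399 higher and 2488 lower, of which 1392 and 1203 changed at least 2-fold. The groups did not overlap for 4312 genes, 41.2% against 0.794% by chance. Hbb-y and Hba-x, embryonic globins, were at least 782-fold and 644-fold higher (adjusted p = 2.7e-14 and 4.11e-10). Ctsj, a placental cathepsin, was at least 577-fold higher, Ceacam11 at least 467-fold, Psg21 at least 458-fold, Prl2b1, a placental prolactin-family hormone, at least 371-fold, and Rhox9, a reproductive homeobox gene, at least 347-fold. Prl8a2 of the decidua was at least 320-fold and Apoa1, an apolipoprotein, at least 309-fold higher. Each of these 9 genes was not above background on the non-pregnant arrays. Sct, the hormone secretin, rose by 9.12 (SE 0.88) on the log2 scale, a 558-fold difference, and was above background on 3 non-pregnant arrays.

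The largest falls were Plekhs1 (log2 fold change -6.57, SE 0.40), P2ry14, a receptor for UDP sugars (-6.35, SE 0.58), Fxyd4, an ion transport regulator (-6.04, SE 0.59), Sprr2f, an oestrogen-induced epithelial gene (-6.04, SE 0.70), Ccl11, eotaxin (-5.62, SE 0.57), Cbr2, a carbonyl reductase (-5.55, SE 0.40), and Adipoq, the fat hormone adiponectin (-5.43, SE 0.49). Retnlg, a myeloid secreted protein, Cyp2e1, a cytochrome P450, and Bcl2l15 were not above background on the PBS arrays and were at least 56.6-fold, 27.7-fold and 24.6-fold lower. Plekhs1, Fxyd4 and Ccl11 were above background on 1 PBS array each and Adipoq on 3. Limma adjusted p-values of these 10 genes were 1.15e-05 or lower. P2ry14 was at 10.22 on non-pregnant array 2 and between 13.08 and 13.93 on the other non-pregnant arrays.

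Of the 28 lists, camera called 13 between PBS and non-pregnant arrays, 6 higher and 7 lower. Trophoblast and placental genes rose with a median of 6.08 (5.72 with members at their bound), and 21 of 22 members passed (adjusted p = 1.86e-10; adjusted p = 0.528 with an estimated correlation). Igf2, a fetal growth factor, rose by 5.65 (SE 0.42), and Phlda2, an imprinted placental gene, was at least 82.7-fold higher. Erythroid and yolk sac genes rose with a median of 6.84 (6.07 at their bound) and 12 of 12 members passed (adjusted p = 1.86e-10; adjusted p = 0.402 with an estimated correlation). Alas2, the erythroid enzyme of haem synthesis, rose by 4.94 (SE 0.36). Liver and pancreas genes rose in 7 of 8 members and fell in 1 (median 5.68, 4.97 at their bound, adjusted p = 0.000578, or adjusted p = 0.528 with an estimated correlation). Those that rose included Ttr (8.53, SE 0.67) and Apoa2 (7.93, SE 0.84), which the yolk sac also makes and which were above background on 2 and 1 non-pregnant arrays.

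Cell cycle genes rose in 15 of 23 members with a median of 1.04 (adjusted p = 0.000162; adjusted p = 0.568 with an estimated correlation), among them Rrm2, a subunit of ribonucleotide reductase, by 3.80 (SE 0.40). Glycolysis and hypoxia genes rose in 11 of 22 members and fell in 2, with a median of 0.55 (0.51 at their bound, adjusted p = 0.0118; adjusted p = 0.528 with an estimated correlation), and Slc2a1, a glucose transporter, rose by 3.37 (SE 0.25). Cholesterol and steroid synthesis genes rose in 7 of 14 members and fell in 1, with a median of 1.11 (adjusted p = 0.0142; adjusted p = 0.568 with an estimated correlation). Cyp17a1 and Cyp11a1, enzymes of steroid hormone synthesis, were at least 16.6-fold and 7.94-fold higher, while Hsd11b2, which inactivates glucocorticoids, fell by 2.61 (SE 0.35).

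Macrophage and monocyte genes fell in 14 of 16 members and rose in 1, with a median of -1.91 (adjusted p = 4.23e-07, or adjusted p = 0.402 with an estimated correlation). Genes of the placenta and embryo were far higher in the PBS samples. For this and the other lists that fell with pregnancy, a smaller share of maternal tissue was not tested and cannot be told apart. C1qc, a chain of complement C1q, fell by 3.02 (SE 0.25) and Ms4a7, a surface protein of macrophages, fell by 3.25 (SE 0.27). In the dendritic cell and MHC class II list 9 of 13 members fell and 2 rose, with a median of -1.71 (-1.58 at their bound, adjusted p = 0.00908; adjusted p = 0.528 with an estimated correlation). Cd74, the invariant chain, fell by 4.10 (SE 0.54) and H2-Aa fell by 3.97 (SE 0.41). Interferon gamma response and MHC class I genes fell in 12 of 20 members, with a median of -1.22 (adjusted p = 0.000162; adjusted p = 0.554 with an estimated correlation), and Irgm2 among them fell by 1.80 (SE 0.29). T cell genes fell in 6 of 9 members and rose in 1, with a median of -0.66 (-0.54 at their bound). Their adjusted p in camera's test was 0.0334, or 0.554 with an estimated correlation. Thy1, a surface glycoprotein of T cells and stroma, fell by 2.01 (SE 0.42). That list call was lost without non-pregnant array 2 (median -0.66). The 4 measured B and plasma cell genes included Fcrla, which was not above background on the PBS arrays and at least 1.85-fold lower, and Sdc1, which fell by 1.09.

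Adipocyte genes fell in 6 of 7 members and rose in 1, with a median of -3.24 (-2.81 at their bound, adjusted p = 0.00908, or adjusted p = 0.554 with an estimated correlation). Extracellular matrix genes fell in 15 of 27 members and rose in 2, with a median of -0.77 (adjusted p = 0.0118; adjusted p = 0.635 with an estimated correlation), and Col6a1, a collagen VI chain, fell by 2.77 (SE 0.46). Smooth muscle genes fell in 11 of 18 members, with a median of -1.36 (adjusted p = 0.0118; adjusted p = 0.635 with an estimated correlation). Myl9, a myosin light chain, fell by 2.59 (SE 0.40), while Actc1, cardiac actin, was at least 62.3-fold higher.

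The other 15 lists did not pass (adjusted p = 0.0543 to 0.913). NK cell and granule genes went both ways, with 6 up and 6 down. Gzmg and Gzme, granzymes of uterine NK cells, were at least 68.4-fold and 29.9-fold higher, and Il15, a cytokine that sustains NK cells, fell by 3.40 (SE 0.45). Decidual genes also went both ways with 6 up and 6 down. Cited2, a transcriptional coregulator, rose by 3.32 (SE 0.35) and Pgr, the progesterone receptor, fell by 2.82 (SE 0.50). Neutrophil genes had a median of 0.79 (0.18 at their bound, -0.25 to 0.89 over 28 other settings) and a mean of -0.11. Camera's direction was up (adjusted p = 0.913) and fry's direction down (adjusted p = 2.64e-05). S100a8, a calcium-binding protein of neutrophils, rose by 5.62 (SE 0.65), while Retnlg and Ltf, lactotransferrin, fell. Regulatory T cell genes had a median of 0.00 and a mean of 0.02 with camera's direction down, immediate early genes a median of -0.03 and a mean of -0.06 with direction up, and endothelial genes a median of -0.36 and a mean of 0.07 with direction down. Other medians were -0.90 for mast cell and eosinophil, -0.58 for type I interferon response and -0.73 (-0.38 at their bound) for cytokine genes. Chemokine genes had -1.18, tolerance and checkpoint genes 0.63 and complement genes -0.44. Medians were -0.74 for contraction-associated, -0.70 for endometrial epithelial and 1.27 (0.89 at their bound) for skeletal muscle genes. Cytokine genes passed without non-pregnant array 1 and without PBS array 4 (median -0.79 in both). With an estimated correlation camera called 0 of the 28 lists, and fry called 19. Median scaling gave 3465 genes, 65.5% of them higher against 49.1% with quantile normalization, and shifted the median of all genes to 0.159. The 13 lists that passed kept the sign of their median in all 28 other settings, though settings that changed only the test could not change it.

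**Figure D2:**
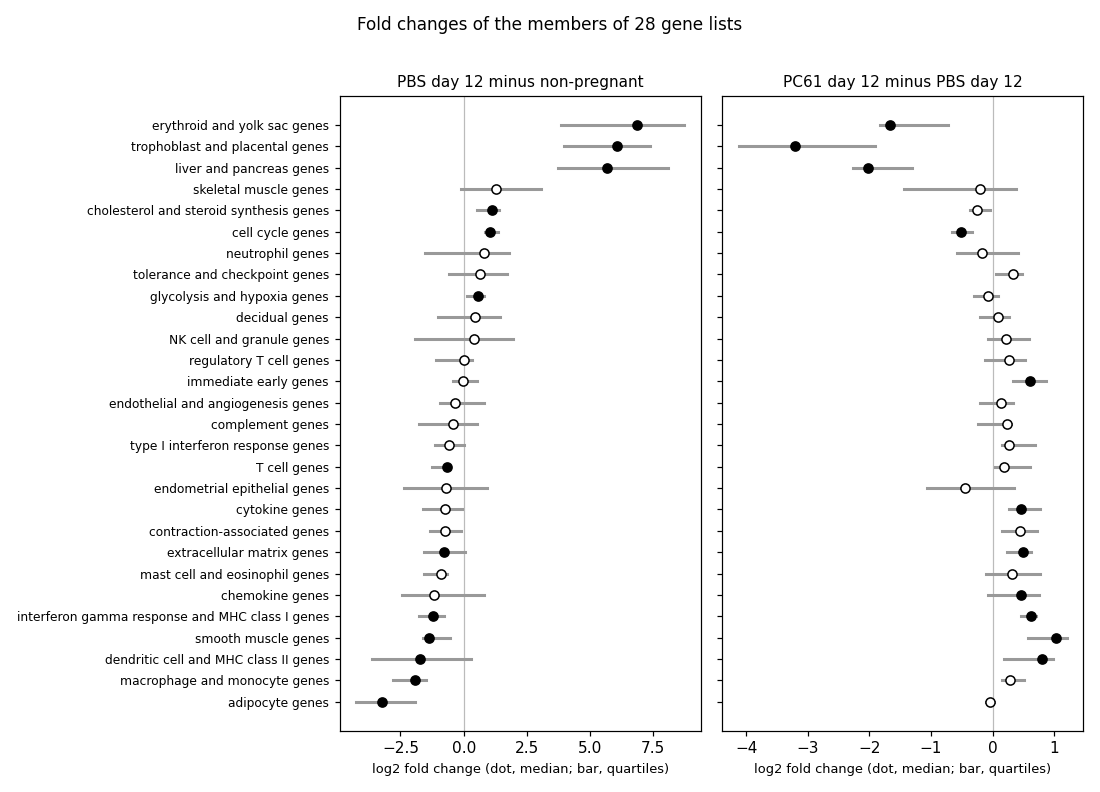
Log2 fold changes of the members of 28 gene lists, with the median as a dot and the quartiles as a bar; filled dots mark lists past camera's threshold at the preset correlation. In the left panel, PBS minus non-pregnant, the trophoblast and placental median was 6.08, and in the right panel, PC61 minus PBS, it was -3.21.

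PC61-treated pregnant uterus was also set against non-pregnant uterus, and limma called 2961 genes, 1434 higher and 1527 lower, and 1794 with median scaling. The groups did not overlap for 2250 genes, 21.5% against 1.59% by chance. Erythroid and yolk sac genes rose in 11 of 12 members (median 4.82, 4.47 at their bound, adjusted p = 2.2e-10; adjusted p = 0.255 with an estimated correlation). Trophoblast and placental genes rose in 8 of 22 (median 2.80, 2.12 at their bound, adjusted p = 4.35e-05; adjusted p = 0.762 with an estimated correlation), and macrophage genes fell in 14 of 16 (median -1.72, adjusted p = 1.02e-07; adjusted p = 0.255 with an estimated correlation). Of the called genes 1287 were higher and 1386 lower in both pregnant groups, and 0 were called in opposite directions. Independent lists of these sizes would share 328 and 363. Unchanged groups simulated against the shared non-pregnant arrays shared 0 genes, which holds where no effect is put in and gives no measure of the overlap. The log2 fold changes of both pregnant groups correlated across genes with r = 0.919 and a covariance of 1.18, against 0.472 and 0.0450 in the simulations. With the non-pregnant arrays split between them, r was 0.884, the covariance 1.16 and the median overlaps 364.5 and 284. The split fits rest on fewer non-pregnant arrays, and the overlap of independent lists of their sizes was not computed. Their overlaps therefore cannot be set against 328 and 363.

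The last comparison asked whether the PC61 effect ran along or against the change with pregnancy. Of 2399 genes that rose with pregnancy, 79.8% were lower in the PC61 than in the PBS group, with a median of -0.31. Of 2488 that fell, 85.1% were higher, with a median of 0.282. These shares use the same PBS arrays on both sides, which alone pushes them this way. With no PBS array on both sides, the log2 fold changes of 10478 genes correlated negatively, with a median Spearman rho of -0.500 (-0.573 to -0.430 over 20 splits), Pearson's r of -0.617 and a covariance of -0.433. Unchanged groups gave 0.000229 in simulations with split arrays and -0.110 with shared arrays, where the observed rho was -0.599. The covariance with shared arrays was -0.450, against -0.0447 simulated. For single PC61 arrays 1 to 4 the split rho was -0.229, -0.454, -0.522 and 0.167, and for single PBS arrays it lay between -0.0125 and 0.0338. A different tissue make-up of the PC61 samples could also give a negative relation. The relation does not separate that from an effect of PC61 on the uterus, and neither was tested.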

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

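The tests of signal, normalization, conceptus share, tissue parts and maternal share were chosen only after the results they bear on were seen, and the test of the label of PC61 array 4 after its likeness to the PBS arrays was seen but before its value was computed. In 10 of 183 groups of 4 or 5 arrays, the highest or lowest array stood apart from the others, where chance gives this in about 5% of groups, or 1 in 20. On PC61 array 4 the smooth muscle level was -0.64 against 1.19 to 1.34 on the other PC61 arrays, Slc5a3 was at 5.31 against 6.53 to 6.72, and Snx32 at 5.85 against 6.33 to 6.38. Prl8a2 was at 5.80 on PC61 array 1 against 13.54 to 13.60, and Unc5b at 6.65 on PC61 array 2 against 7.42 to 7.57. Ugt3a2 was at 6.60 on PBS array 3 against 5.98 to 6.11 on the other PBS arrays. Among non-pregnant arrays, P2ry14 was at 10.22 on array 2 against 13.08 to 13.93, Pdap1 at 11.23 on array 2 against 10.48 to 10.69, and the endometrial epithelial level at 0.84 on array 2 against 0.47 to 0.57. The cytokine level was 0.51 on non-pregnant array 1 against 0.63 to 0.66.

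The PC61 arrays differed from each other more than arrays within the other groups, with a median SD of 0.403 against 0.242 and 0.251. Lower signal is argued against for PC61 arrays 2 and 3, since 0 of these 2 had fewer detected probes than every PBS array (19136 and 18378 against 17799 to 19552), though the median intensity of array 2 was 114 against 120 to 139. PC61 array 1 had fewer, at 17483, but signal loss as its whole cause is argued against, since it would lower 2 abundant lists alike, and the trophoblast level lay -4.81 from the erythroid level there, against up to 0.20 on a PBS array. A wrong label on PC61 array 4 stays open: among 6 arrays, it and the 5 PBS arrays, it was the highest or lowest in 34.9% of genes, within the 24.9% to 43.5% of the PBS arrays, against 57.6%, 62.9% and 64.1% for PC61 arrays 1 to 3 tested the same way. A treated mouse that did not respond could give this value too. The smooth muscle (-0.64), extracellular matrix (-0.60), trophoblast (0.61) and MHC class II (-0.33) levels lay outside the range of the PBS arrays. So did the relation of 0.167. The NK cell (-0.05), interferon gamma response (-0.07), cytokine (0.00), erythroid (-0.01) and decidual (-0.20) levels lay inside it. Any 1 of 6 like arrays is the highest or lowest in 33.3% of genes by chance, so these picked levels do not decide between a wrong label and no response. Unequal response to PC61 between mice stays open and was not tested.

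Placental and embryonic genes were lower in the PC61 group, with a trophoblast median of -3.21. Erythroid levels were -0.12, -2.81, -2.46 and -0.01 on PC61 arrays 1 to 4, so their fall lay on arrays 2 and 3. The normalization is argued against as the cause, since the medians under the other settings of background and scaling lay between -3.55 and -2.56. One smaller share of conceptus tissue for all of its genes is argued against for PC61 arrays 1 and 2, where the trophoblast and erythroid levels differed by -4.81 and -2.02, in 2 of 2 by more than the 0.61 on PC61 array 4, which had no fall, and the 0.20 on a PBS array. It stays open for PC61 array 3, at -0.40. That is more than on any PBS array and less only than on PC61 array 4, whose label is in doubt. Similar list levels do not show that single genes fell alike. Different parts of the pregnant uterus in single samples may give such values, with an SD of the trophoblast level of 2.59 against 0.21 between PBS arrays, and cannot be told apart from effects of PC61 of unequal size, because the part taken for each sample is not given in the sources used here. Loss of the conceptus after PC61 is a hypothesis that stays open and was not tested.

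Interferon gamma response, cytokine, chemokine, MHC class II and smooth muscle genes were higher in the PC61 group as lists. This held in camera's test at the preset correlation, and 0 lists passed with an estimated correlation. A larger share of maternal tissue that raises all maternal genes alike is argued against on PC61 array 1. Smooth muscle genes were at 1.24 there and NK cell genes at -2.33. It stays open on PC61 arrays 2 and 3. The decidual, smooth muscle, macrophage, NK cell and neutrophil levels spanned 3.56, 1.28 and 1.24 on PC61 arrays 1 to 3. These are the 3 with higher smooth muscle levels. In 3 of 3 the span was above the 0.59 on PC61 array 4 and the 0.49 reached by a PBS array. But it was 2.55 to 3.02 on the non-pregnant arrays, so maternal tissue alone can give wide spans. Retnlg in the neutrophil list was not above background on the PBS arrays, so it shows little of a rise. A change in the make-up of the maternal tissue might also give the higher lists. An effect of PC61 on immune cells stays open, and neither was tested. Whether regulatory T cells were depleted is not settled by these values. Levels of the regulatory T cell list were -0.92, 0.40, 0.66 and -0.07 on PC61 arrays 1 to 4. Smooth muscle was at -0.64 on PC61 array 4, so that list was not higher on every PC61 array. The immune levels were raised mainly on PC61 arrays 2 and 3. On PC61 arrays 1 to 4 interferon gamma response genes were at -0.35, 1.18, 1.44 and -0.07. Cytokine genes were at 0.17, 1.03, 1.22 and 0.00, and chemokine genes at -0.01, 0.74, 0.95 and -0.06. MHC class II genes were at 0.09, 0.76, 1.01 and -0.33.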

How the results depend on the processing

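The fit without the 2 arrays of lowest median signal, non-pregnant array 3 and PC61 array 1, was chosen after seeing the data, and the other alternatives before. Between PC61 and PBS, the 0 genes became 303 with median scaling, 4039 with array weights and 2 without the 2 arrays of lowest signal, and 0 to 1528 with 1 array left out, with the highest value without PC61 array 4 and 2 without PC61 array 1. The 11 lists became 18 with median scaling, 18 with array weights, 17 without the 2 arrays of lowest signal, 0 with an estimated correlation, 0 with fry, and 8 to 17 with 1 array left out, lowest without PC61 array 3 and highest without PC61 array 1. Between PBS and non-pregnant arrays, the 4887 genes became 9075 with every kept probe tested and 2595 at 2-fold or more, by construction of these settings, and 4391 to 5251 with 1 array left out. The 13 lists became 0 with an estimated correlation and 12 to 14 with 1 array left out, and fry called the neutrophil list down (median 0.79). Between PC61 and non-pregnant arrays, the 2961 genes became 1794 with median scaling, 5328 with every kept probe, 1621 at 2-fold or more, 1722 at an adjusted p under 0.01, and 2406 to 3094 with 1 array left out. The relation of -0.500 became -0.658 over genes past the threshold for pregnancy, -0.599 with shared PBS arrays, where shared error adds to it, -0.447 without the 2 arrays of lowest signal, and -0.539 to -0.427 with 1 array left out. Where construction does not show it, the cause was not tested.

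With the replicate number as a replicate block there were 0, 4770 and 2621 genes, 14 and 13 lists and a relation of -0.518. Arrays of the same number deviated together with a median r of 0.0538 (-0.175 to 0.333 over 13 pairs, 4 of them over 0.1), so the numbers were not read as pairs. For named genes between PC61 and PBS, 2910 values stayed on their side of the threshold, 200 passed it (73 without PC61 array 4, 22 with median scaling, the others with array weights) and 22 moved. For those between PBS and non-pregnant arrays, 3054 stayed, 31 were lost, 8 were gained and 4 moved. Counted over pairs of a list and a setting, list results between PC61 and PBS stayed in 682, were lost in 34, gained in 43 and moved in 25. Between PBS and non-pregnant arrays these were 745, 17, 13 and 8, and 1 was reversed. That 1 was the direction of fry's test for the neutrophil list, whose median stayed at 0.79 there. Slide as a block was not run. Genes near background have only bounds.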

Other observations

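The following values were looked at after the list results were seen, and the counts over other splits of the arrays were planned. The PC61 arrays held different combinations of low and high lists. On PC61 array 1 trophoblast genes were at -4.93, NK cell genes at -2.33 and decidual genes at -1.14, while erythroid genes were at -0.12 and skeletal muscle genes at 1.12. Gzmd, a granzyme of uterine NK cells, and Prl8a2, a decidual hormone, were at 4.83 and 5.80 there, and Ttn, the muscle protein titin, was at 9.10. On PC61 arrays 2 and 3 erythroid genes were at -2.81 and -2.46, skeletal muscle genes at -1.47 and -1.24 and liver and pancreas genes at -3.66 and -2.33, while NK cell genes were at 1.29 and 1.21 and type I interferon response genes at 1.06 and 1.10. Ttn was at 4.65 and 4.34 on these arrays, and at 7.81 to 8.42 on the PBS arrays.

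Some members of lists that did not pass changed between PBS and non-pregnant arrays. These lists were tolerance and checkpoint (adjusted p = 0.441), regulatory T cell (0.589), cytokine (0.0543), endothelial (0.502) and endometrial epithelial (0.216) genes. Tgfb2, a transforming growth factor, rose by 2.68 (SE 0.31) and Tnfrsf9, a costimulatory receptor, rose by 4.86 (SE 0.80), while Cd200, an inhibitory ligand, fell by 3.21 (SE 0.27) and the cytokine Il33 fell by 2.40 (SE 0.20), each with a limma adjusted p of 0.000221 or lower. Angpt2, a vessel growth factor, rose by 3.23 (SE 0.54) and Emcn, an endothelial surface protein, fell by 1.27 (SE 0.15). Wnt7a and Ovgp1, genes of the uterine and oviductal epithelium, fell by 2.78 (SE 0.25) and fell by 4.68 (SE 0.53). Non-pregnant arrays 1 to 5 were spread in cell cycle genes, at -0.75, -2.06, -0.90, -0.72 and -1.46, and in adipocyte genes, at 2.00, 4.58, 1.92, 3.41 and 2.67. Hdc, the histamine-forming enzyme, was at 11.65, 13.85, 10.15, 11.02 and 13.21 on the same arrays.

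Other splits of the same arrays into groups of the same sizes were counted, with the real split among 100. For genes between PBS and non-pregnant arrays, 1 of 100 splits reached 4887 and the highest other gave 0. Chance in the sorting of these arrays can therefore be excluded. Chance between animals cannot, since nothing says that the samples came from separate animals. Between PC61 and non-pregnant arrays, 1 of 100 reached 2961 and the highest other gave 1206, so chance in the sorting can be excluded there too. That split and the others at 796 and 632 kept the 4 PC61 arrays together with 1 non-pregnant array. For genes between PC61 and PBS arrays, 100 of 100 splits reached the real count of 0, which any split does, so this count tells nothing about chance, and the highest other gave 849. The 4 splits with over 100 genes, at 849, 516, 330 and 297, each put 1 PBS array in the place of PC61 array 4, which points to a structure of the samples. For lists, 38 of 100 splits reached the real 11 between PC61 and PBS (highest other 22) and 5 of 100 the real 13 between PBS and non-pregnant arrays (highest other 14). The relation of -0.500 was reached by 5 of 100 (furthest other -0.539). These shares do not exclude chance for the 3 results. Where 5 of 100 reached the real value, the 4 other splits were each 1 exchange away from the real one, with non-pregnant array 1 in the place of a PBS array, or a PBS array in the place of PC61 array 4.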
